A study of Mus musculus with 12 samples.

How the data were processed

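Total RNA of BMEL cells was measured on 12 Affymetrix mouse 430A arrays, with 2 arrays for each combination of the lines 9A1 and 14B3 and of basal, aggregate and Matrigel culture. Per the labels, RNA was extracted on columns, checked for integrity on electropherograms, and turned into biotin-labelled cRNA from 5 ug. The deposited values are RMA signal intensity per probe set, made by the authors with R 2.3.1 and RMA. They run from 14.4 to 27318 on a linear scale, although RMA gives log2 values, so the log2 of each value was taken before any test. Depth is not counted on arrays, so the number of arrays limits the precision. The design calls the arrays duplicate biological replicates and gives no more on how the cultures were kept apart, so p-values measure only the spread between these samples, which may hold technical spread alone.

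Probe sets were named by the platform annotation that GEO gives, which can be old, and symbols were matched by gene ID to a mouse gene table. Of 22690 probe sets, 20380 carried 1 symbol, 691 several and 1555 none, and 64 were controls; the last 3 kinds were left out of the gene tests. Each gene was represented by its brightest probe set over the 12 arrays, which left 12393 genes, of which 4956 had more than 1 probe set. No filter on dim genes was applied.

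The log2 values were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with a mean for each of the 6 groups, which left 6 residual degrees of freedom and a median residual SD of 0.170. Contrasts were aggregate minus basal, Matrigel minus basal and Matrigel minus aggregate, each averaged over the lines, 14B3 minus 9A1 averaged over cultures, and the difference between lines in each response to culture. Gene p-values were adjusted by Benjamini-Hochberg over all genes at 0.05. Tests were two-sided. On simulated data with 200 changed genes per draw, 54.0% of genes changed by 0.5 log2 units were called. Of those changed by 1 and by 2, 98.5% and 100% were called, and 5.33% of calls were false. The simulated arrays had independent noise and no difference by replicate number, so these rates may not hold for the real arrays.

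A set of 22 gene lists was written before the data were examined, as were the contrasts, the tests, most alternatives and the rule for named genes. The lists were hepatocyte secreted proteins, hepatocyte enzymes and transporters, liver transcription factors, bile duct, progenitor surface and general surface genes, proliferation, matrix, junctions, haematopoietic, endothelial and stellate cells, cholesterol synthesis, hypoxia, interferon, acute phase, oxidative stress, unfolded protein stress, immediate early, imprinted and sex-linked genes, and TGF-beta, Wnt and Hippo targets. The 21 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 between genes, adjusted over 84 tests (21 lists in 4 contrasts). With an estimated correlation 0 of the 84 passed. The fry test, which asks only whether a list's genes move on balance one way, passed 15, 11, 9 and 6 lists for the 4 contrasts in the order given above. Named genes were the 6 largest rises and falls per contrast that passed, had the same direction in each line (for the line contrast, each culture) and did not overlap between arrays; up to 3 called members of each passing list and 1 of each other list; up to 5 called surface genes per direction; 12 marker genes fixed by name; the 4 largest differences in response per direction; and up to 15 called surface genes higher in basal culture.

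Whether replicate numbers pair the samples was checked on the data: the differences between replicate 2 and replicate 1 correlated across genes between groups in all 15 pairs of groups, with r from 0.10 to 0.64. A fit with the replicate number as a block within each line is therefore given beside a result where it changes the call or moves a count by over 1.5 times. Other alternatives were leaving out each array in turn, other scalings of the arrays, the mean of a gene's probe sets, every probe set, genes above the median level, a change of at least 1 log2 unit, array weights, an additive fit, culture alone and each line alone. Chosen after seeing the data were a block shared by both lines, the arrays of 1 replicate number only, leaving out both arrays in doubt, and the block with an estimated correlation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.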

Results

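RNA levels were measured on 12 one-colour arrays from bipotential mouse embryonic liver (BMEL) cells, immortal lines derived from embryonic liver that can take on hepatocyte or bile duct features in culture. The independently isolated lines 9A1 and 14B3 were each grown in basal culture, as floating aggregates and in Matrigel, a basement membrane gel. Per the labels aggregates were grown for 5 days and Matrigel cultures for 10 days, except Matrigel_14B3 replicate 1, given as 5 days. The 6 groups of line and culture held 2 arrays each, so each culture had 4 arrays and each line 6. Values were signal intensities, with a median per array of 268 to 281 over 22690 probe sets, and the number of arrays limits their precision. Culture separated the arrays most: the first principal component held 68.0% of the variance over 12393 genes, with the basal arrays at 43.8 to 59.4, the Matrigel arrays at -10.1 to 0.60 and the aggregate arrays at -54.1 to -43.3. Averaged over genes, culture accounted for 75.6% of the sum of squares, line for 8.65% and the replicate number for 4.69%.

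**Figure D1:**
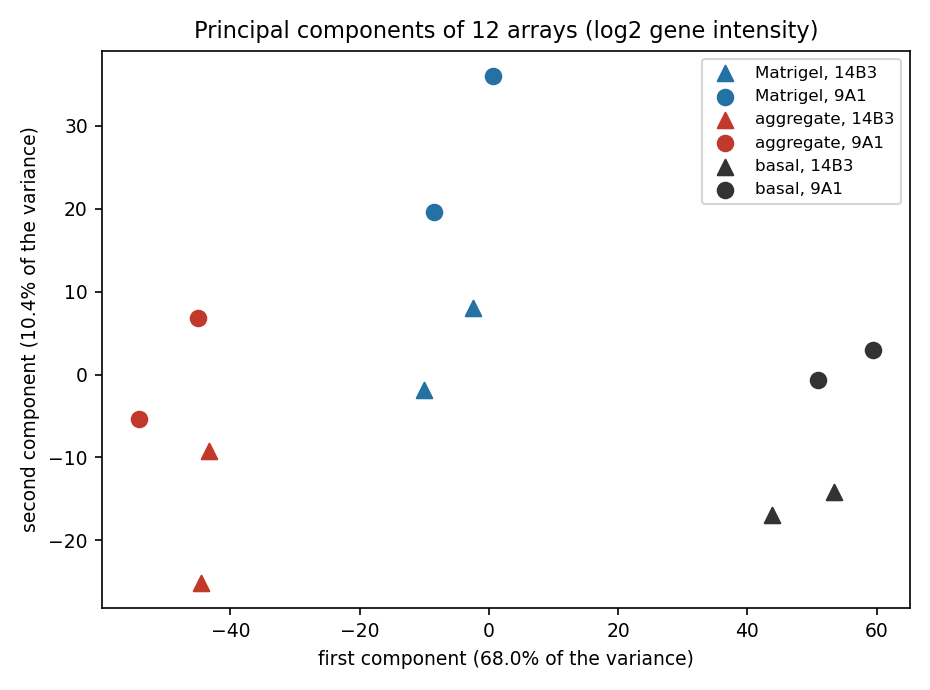
Scores of the 12 arrays on the first (68.0% of the variance) and second (10.4%) principal components of log2 gene intensity; colour gives the culture and shape the cell line. The basal arrays lie at 43.8 to 59.4 on the first component and the aggregate arrays at -54.1 to -43.3, with the Matrigel arrays between them.

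Aggregates were compared with basal culture to ask what changes when the cells leave the state that the labels call basal. Lypd8, a membrane-anchored protein of gut epithelium (Entrez Gene 70163), went from a mean log2 intensity of 6.43 ± 0.31 (SD, n = 4) to 13.94 ± 0.09 (SD, n = 4), 183-fold. Ugt2b5, a glucuronosyltransferase (Entrez Gene 22238), rose 183-fold, the fatty acid binding protein gene Fabp2 140-fold, the carboxylesterase gene Ces2a 108-fold, Cyp2d26 102-fold and Clec2h 91.1-fold. Their basal levels, 5.15 (Ugt2b5) to 6.90 (Ces2a), lie among those of 33 kidney, lung and pancreas genes with no call between cultures or lines (4.92 to 9.28 over the arrays). They may be background, so these folds can be too small and their order is not settled. The same holds below for every rise, fall or difference whose lower level lies in this range. The range is a loose guide only. The 33 genes may themselves be expressed, and its top lies above the median gene level of the arrays (8.38 to 8.46). A level within it may thus also be real signal. The thrombin receptor gene F2r (Entrez Gene 14062) fell from 12.56 ± 0.23 to 6.76 ± 0.48 (SD, n = 4 each), 55.9-fold lower, and the serine synthesis gene Psat1 was 50.4-fold lower, to 6.30; both end in the same range. The caveolin gene Cav1 fell by 4.64 on the log2 scale, the cardiac troponin gene Tnnt2 was 24.7-fold lower and the gap junction gene Gja1 20.1-fold lower. All 12 of these changes had the same direction in both lines, with adjusted p from 2.54e-12 (Ugt2b5) to 4.07e-08 (Rrm2, a ribonucleotide reductase subunit, 26.3-fold lower).

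Hepatocyte genes rose as groups in the aggregates. Of 39 measured secreted hepatocyte proteins 28 rose and 0 fell, 29 rose when adjusted over the list alone (median log2 change 1.12, adjusted p = 2.37e-08; adjusted p = 0.419 with an estimated correlation). Among them the lipoprotein genes Apoc3, Apoc2 and Apoa1 rose 66.1-, 64.6- and 41.4-fold from basal levels in the range above (6.48, 7.65 and 9.06), and albumin (Alb, Entrez Gene 11657) rose by 4.38 ± 0.43 on the log2 scale (SE, 4 against 4 arrays, adjusted p = 4.07e-06). The fetal albumin relative Afp rose by 2.08 ± 0.28 (SE), with 3.73 in 9A1 and 0.43 in 14B3. The median of the secreted protein list was 1.58 in 9A1 and 0.43 in 14B3. Of 41 hepatocyte metabolic enzymes and transporters 23 rose and 0 fell, 25 adjusted over the list alone (adjusted p = 2.3e-07; adjusted p = 0.342 with an estimated correlation). The retinal dehydrogenase gene Aldh1a1 rose 76.8-fold, Fabp1 57.9-fold and Cyp2c29 27.0-fold, again from that range (7.48, 8.39 and 7.46). Of 22 liver-enriched transcription factors 14 rose and 4 fell, 15 and 4 adjusted over the list alone (adjusted p = 0.0139; adjusted p = 0.402 with an estimated correlation). The nuclear receptor genes Nr1i2 and Nr1h4 rose by 2.23 and 1.80 on the log2 scale and Hnf4a by 0.94, while Foxa1 fell by 1.78.

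Cell division genes fell together in the aggregates. Of 42 proliferation genes 40 fell and 0 rose, also 40 adjusted over the list alone, with a median of -2.71 (adjusted p = 8.12e-25; adjusted p = 0.183 with an estimated correlation). Rrm2, the survivin gene Birc5 (16.4-fold lower) and the proliferation marker Mki67 (15.6-fold lower) were the strongest. Of 53 extracellular matrix and mesenchymal genes 25 fell and 2 rose, 25 and 3 adjusted over the list alone (adjusted p = 0.00068; adjusted p = 0.342 with an estimated correlation). The fibulin gene Fbln2 was at -3.86, the laminin gene Lamb1 at -3.09 and Tgfbi at 3.46. Of 23 targets of the TGF-beta, Wnt and Hippo pathways 12 fell and 2 rose, the same numbers adjusted over the list alone (adjusted p = 0.00324; adjusted p = 0.373 with an estimated correlation). They include the cyclin gene Ccnd1 (-3.37), Ankrd1 (-3.03) and Ccn2 (-2.42).

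Further groups rose in the aggregates. Of 29 genes of oxidative stress and glutathione 20 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 1.38e-05; adjusted p = 0.235 with an estimated correlation). The glutathione transferase genes Gsta3 (4.79) and Gsta2 (4.69) led them. Of 29 hypoxia and glycolysis genes 21 rose and 2 fell, 22 and 2 adjusted over the list alone (adjusted p = 0.000922; adjusted p = 0.658 with an estimated correlation). Ndrg1 was at 2.53 and Bnip3 at 2.16. Of 28 interferon response genes 15 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.00324; adjusted p = 0.529 with an estimated correlation). The RNA sensor gene Ifih1 was at 1.99. Of 19 cholesterol synthesis genes 12 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.0181; adjusted p = 0.751 with an estimated correlation), with Tm7sf2 at 2.29. In the acute phase and complement list 10 of 29 genes rose and 1 fell, with the complement factor gene Cfb at 2.74 (adjusted p = 0.0449; adjusted p = 0.794 with an estimated correlation). That call ended with the replicate block (adjusted p = 0.0538) and without basal_9A1 replicate 1 (0.093), basal_14B3 replicate 1 (0.0755), aggregate_14B3 replicate 2 (0.0543) or Matrigel_14B3 replicate 1 (0.0522).

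Markers of other cell types and epithelial junction genes did not pass as lists in the aggregates. Of 27 bile duct genes 10 rose and 7 fell (adjusted p = 0.636): Epcam rose 31.9-fold, Krt7 fell by 2.29 on the log2 scale, and Krt19 was at -0.27 (adjusted p = 0.0784, but 0.0469 without basal_9A1 replicate 2 and 0.0209 without aggregate_9A1 replicate 2). Of 36 genes of epithelial junctions and keratins 19 rose and 6 fell (adjusted p = 0.0529, median 0.48). That list passed without basal_9A1 replicate 2 (0.0328), basal_14B3 replicate 2 (0.0357), aggregate_9A1 replicate 2 (0.0414) or aggregate_14B3 replicate 2 (0.0273). Of 24 haematopoietic genes 3 rose and 0 fell (adjusted p = 0.111), of 23 endothelial genes 2 rose and 0 fell (adjusted p = 0.384), and of 15 hepatic stellate cell genes 2 rose and 2 fell (adjusted p = 0.908). The lists of unfolded protein and amino acid stress (8 of 28 rose and 12 fell, adjusted p = 0.106), immediate early genes (13 of 25 rose and 6 fell, adjusted p = 0.431) and imprinted genes (3 of 21 rose and 4 fell, adjusted p = 0.927) did not pass either.

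Over all 12393 genes, 2841 were higher and 2894 lower in aggregates than in basal culture at an adjusted p below 0.05, 46.3% of the genes, and 877 and 1058 of these changed by at least 1 log2 unit. Within 9A1 alone 4567 genes passed and within 14B3 alone 4109.

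The Matrigel cultures were compared with basal culture for the same question. The strongest rises again included Lypd8 (132-fold), Ugt2b5 (84.1-fold), Fabp2 (75.3-fold), Apoc3 (61.7-fold), Apoc2 (61.0-fold) and Cyp2d26 (60.5-fold), from basal levels in the range of the kidney, lung and pancreas genes above. The cell adhesion gene Epcam (Entrez Gene 17075) went from a mean log2 intensity of 7.67 ± 0.20 to 12.41 ± 0.28 (SD, n = 4 each), 26.6-fold higher. Among the falls, the aldehyde dehydrogenase gene Aldh3a1 was 10.2-fold lower, Clca3b 9.84-fold lower and the surface protein gene Cd109 6.53-fold lower, and Fgf13, the chemokine gene Ccl9 and Tnnt2 fell by 3.02, 3.01 and 2.91 on the log2 scale. The Matrigel levels of Aldh3a1 (6.29), Clca3b (7.64), Cd109 (6.52), Fgf13 (7.88), Ccl9 (7.06) and Tnnt2 (7.74) may be background. All of these held in both lines with no overlap between the arrays.

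Hepatocyte groups rose in Matrigel as well. Of 39 secreted proteins 20 rose and 0 fell, 22 adjusted over the list alone (median 1.02, adjusted p = 5.49e-10; adjusted p = 0.384 with an estimated correlation). Apoa4 rose 46.0-fold and Alb by 4.46 ± 0.43 (SE) on the log2 scale. Afp rose by 2.66 on average, by 4.42 in 9A1 and 0.90 in 14B3. The median of the secreted protein list was 1.07 in 9A1 and 0.48 in 14B3. Of 41 metabolic enzymes and transporters 15 rose and 0 fell, also 15 adjusted over the list alone (adjusted p = 5.37e-05; adjusted p = 0.402 with an estimated correlation). Fabp1 was 31.4-fold and the alcohol dehydrogenase gene Adh1 19.5-fold higher. Of 22 liver-enriched transcription factors 10 rose and 2 fell, 11 and 2 adjusted over the list alone (adjusted p = 0.00324; adjusted p = 0.358 with an estimated correlation). Foxa3 was at 1.21, Nr1i2 at 1.14 and Hnf4a at 0.55. Of 29 oxidative stress and glutathione genes 14 rose and 2 fell, 16 and 3 adjusted over the list alone (adjusted p = 5.62e-06; adjusted p = 0.226 with an estimated correlation), with Gsta2 10.7-fold higher.

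Epithelial lists passed in Matrigel against basal culture. For Matrigel against aggregates the list test passed neither the junction list (median -0.05, adjusted p = 0.452) nor the bile duct list (0.24, 0.0553). Passing in Matrigel and not in aggregates thus does not show that the 2 cultures differ. Of 36 genes of epithelial junctions and keratins 17 rose and 3 fell, 19 and 4 adjusted over the list alone (adjusted p = 0.000146; adjusted p = 0.321 with an estimated correlation). The connexin gene Gjb1 rose 9.33-fold and the tight junction gene Ocln by 2.37 on the log2 scale. Of 27 bile duct genes 8 rose and 3 fell, 8 and 5 adjusted over the list alone (adjusted p = 0.0158, but 0.0522 without Matrigel_14B3 replicate 1; adjusted p = 0.358 with an estimated correlation). Its strongest members were Epcam, the microvillus gene Vil1 (9.48-fold) and the chloride channel gene Cftr (2.21 on the log2 scale). The keratin gene Krt7, of the same list, was at -0.81 (adjusted p = 0.0604, but 0.00776 with the replicate block, 0.0122 without Matrigel_14B3 replicate 1 and 0.0223 without either array of aggregate_9A1, replicate 1 or replicate 2). Krt19 was at -0.03 (adjusted p = 0.896), Sox9 at -0.16 (adjusted p = 0.447).

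The proliferation list fell in Matrigel too: 39 of 42 genes fell and 0 rose, 41 adjusted over the list alone, with a median of -1.22 (adjusted p = 9.61e-22; adjusted p = 0.189 with an estimated correlation). Kif20a was at -1.67, Bub1 at -1.66 and Ccnb2 at -1.60. Of 29 hypoxia and glycolysis genes 11 rose and 1 fell, 13 and 1 adjusted over the list alone (adjusted p = 0.000209; adjusted p = 0.607 with an estimated correlation). Ndrg1 was at 1.83. Of 28 interferon response genes 7 rose and 2 fell, 9 and 2 adjusted over the list alone (adjusted p = 0.0158, but 0.0525 without basal_9A1 replicate 1; adjusted p = 0.607 with an estimated correlation). Extracellular matrix genes moved both ways, 9 of 53 up and 10 down (adjusted p = 0.871, median -0.02 and mean 0.04), with the tenascin gene Tnc at 2.72. Cholesterol synthesis had 4 of 19 genes up and 1 down (adjusted p = 0.684, median -0.07 and mean 0.05). That average joins medians of opposite sign, 0.29 in 9A1 and -0.45 in 14B3. Haematopoietic genes (2 of 24 up, 0 down, adjusted p = 0.701), endothelial genes (2 of 23 up, 0 down, adjusted p = 0.807) and stellate cell genes (0 of 15, adjusted p = 0.871) did not pass.

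In all, 1743 genes were higher and 1776 lower in Matrigel than in basal culture (28.4% of the genes), 492 and 255 of them by at least 1 log2 unit. In 9A1 alone 2203 genes passed, but 981 without basal_9A1 replicate 1 and 1339 without Matrigel_9A1 replicate 2; in 14B3 alone 2046 passed, but 907 without basal_14B3 replicate 1 and 1201 without Matrigel_14B3 replicate 2.

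**Figure D2:**
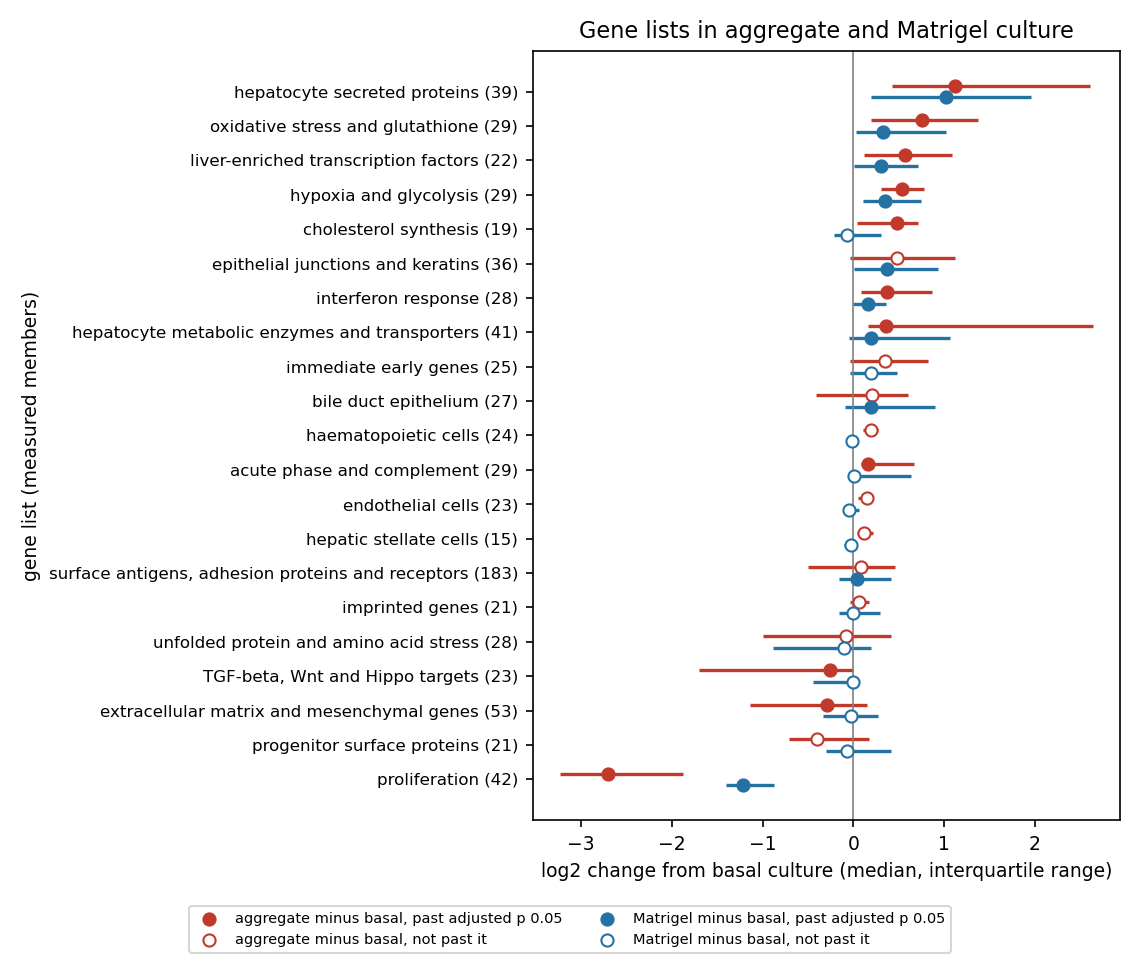
Median (points) and interquartile range (bars) of the log2 change from basal culture over the measured members of each fixed gene list, in aggregates (red) and Matrigel (blue); filled points passed adjusted p 0.05 with the preset correlation, open points did not, and numbers in brackets are measured members. Proliferation lies lowest, with medians of -2.71 and -1.22, and secreted hepatocyte proteins lie highest, with 1.12 and 1.02.

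Matrigel and aggregate culture were then set against each other. Per the labels aggregates were grown for 5 days and all Matrigel cultures but Matrigel_14B3 replicate 1 for 10 days. Differences between these cultures, here and below, therefore cannot be told apart from time in culture. Changes are given as Matrigel minus aggregate. F2r was higher by 4.12 on the log2 scale and Psat1, Rrm2 and the calponin gene Cnn3 by 3.31, 3.25 and 3.23; the aggregate levels of F2r (6.76), Psat1 (6.30), Rrm2 (7.72) and Cnn3 (7.95) may be background. The adenosine deaminase gene Ada had a mean linear intensity of 877 in Matrigel against 67.4 in aggregates, where its level may be background, and Prl2a1, a prolactin family gene, was higher by 3.33. Cyp2c29 was lower by a log2 change of -3.87, Cyp2c55 by -3.28, Ces2a by -3.13, Bcl2l15 by -2.88 and the peptidase gene Anpep by -2.88. Albumin was at 0.08 (adjusted p = 0.893) and Epcam at -0.26 (adjusted p = 0.239), both without a call. Albumin was lower with replicate 1 arrays only (-0.98, adjusted p = 0.0141).

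Of the 42 proliferation genes 36 were higher in Matrigel than in aggregates and 0 lower, 37 adjusted over the list alone (median 1.45, adjusted p = 9.44e-27; adjusted p = 0.183 with an estimated correlation). Birc5 was at 2.85 and Mki67 at 2.68. Of 53 matrix genes 27 were higher and 3 lower, 30 and 5 adjusted over the list alone (adjusted p = 1.09e-08; adjusted p = 0.183 with an estimated correlation). Tnc was at 2.69, Lamb1 at 2.59 and Igfbp7 at 2.55. Of 21 progenitor surface genes 7 were higher and 0 lower, 8 adjusted over the list alone (adjusted p = 0.00045; adjusted p = 0.407 with an estimated correlation): Cd9, Cd24a and Cd44 were higher by 2.18, 2.16 and 2.14, and Dlk1 by 1.23. Of 23 TGF-beta, Wnt and Hippo targets 12 were higher and 2 lower, the same numbers adjusted over the list alone (adjusted p = 0.000425; adjusted p = 0.342 with an estimated correlation). Ankrd1 was at 2.52 and Ccn2 at 2.33.

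Metabolic lists were lower in Matrigel than in aggregates. Of 41 hepatocyte enzymes and transporters 20 were lower and 1 higher, 23 and 1 adjusted over the list alone (adjusted p = 6.36e-07; adjusted p = 0.353 with an estimated correlation). The urea cycle gene Otc was at -2.37. Of 19 cholesterol synthesis genes 11 were lower and 0 higher, 14 adjusted over the list alone (adjusted p = 0.000237; adjusted p = 0.55 with an estimated correlation). Tm7sf2 was at -1.07 and Dhcr7 at -1.04. Of 29 oxidative stress and glutathione genes 13 were lower and 0 higher, 15 and 1 adjusted over the list alone (adjusted p = 0.00068; adjusted p = 0.342 with an estimated correlation). Gsta3 was at -1.56. Of 28 interferon response genes 11 were lower and 0 higher, also 11 adjusted over the list alone (adjusted p = 0.0181; adjusted p = 0.607 with an estimated correlation). Of 39 secreted proteins 9 were lower and 1 higher, the same numbers adjusted over the list alone, with Itih4 at -1.74 and Fga at -1.68 (adjusted p = 0.0208, but 0.343 without aggregate_9A1 replicate 1 and 0.0707 without aggregate_14B3 replicate 1, and 0.819 with the test turned in replicate 2 arrays only; adjusted p = 0.794 with an estimated correlation). Of 24 haematopoietic genes 1 was higher and 1 lower (the macrophage genes Cd68 at 0.72 and Csf1r at -0.88), and the list passed (adjusted p = 0.0334; adjusted p = 0.794 with an estimated correlation) but not without aggregate_14B3 replicate 2 (0.0758), Matrigel_9A1 replicate 1 (0.11) or Matrigel_14B3 replicate 1 (0.109). Its median of -0.21 lies beside a median of -0.10 over all genes. Liver-enriched transcription factors had 3 of 22 higher and 10 lower (adjusted p = 0.119).

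In all, 1728 genes were higher and 1579 lower in Matrigel than in aggregates (26.7% of the genes), 385 and 187 of them by at least 1 log2 unit.

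The series set out to find surface markers of liver progenitor cells, so the surface genes that parted basal culture from both other cultures were compared as a set. Of 183 measured surface antigens, adhesion proteins and receptors, 24 were higher in basal culture than in both others and 36 were lower. These changes were averaged over the lines, and some lay mainly in 9A1. Among the 24, Thbd changed in aggregates by -2.38 in 9A1 and 0.13 in 14B3. Cd34 changed in Matrigel by -1.58 in 9A1 and -0.02 in 14B3. In 7 of the 24 both falls reached 1 log2 unit. Cd109, a GPI-anchored protein (Entrez Gene 235505), had a mean log2 intensity of 9.22 ± 0.38 in basal culture, 5.47 ± 0.07 in aggregates and 6.52 ± 0.58 in Matrigel (SD, n = 4 each), 13.5- and 6.53-fold lower than basal, with both lower levels in the range of the kidney, lung and pancreas genes above. The amino acid transporter gene Slc7a5 was 4.49- and 3.39-fold lower in aggregates and Matrigel, F2r 55.9- and 3.22-fold, the protein C receptor gene Procr 3.17- and 2.69-fold, the glypican gene Gpc1 4.78- and 2.65-fold, the receptor kinase genes Axl 3.76- and 2.28-fold and Epha4 2.98- and 2.11-fold. Next by the smaller fall came Podxl, Fzd6, Jag1, Notch1 and Cd9 with falls of at least 0.87 in both cultures. Icam1 fell by 0.50 in aggregates and 0.39 in Matrigel, and its Matrigel call (adjusted p = 0.0327) ended without basal_9A1 replicate 1 (0.154), basal_14B3 replicate 1 (0.153), Matrigel_9A1 replicate 1 (0.0587), Matrigel_9A1 replicate 2 (0.0839) or Matrigel_14B3 replicate 1 (0.0918).

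Surface genes lower in basal culture than in both others included Epcam. In 15 of the 36 both rises reached 1 log2 unit, among them the complement regulator gene Cd55 (8.93-fold in aggregates and 9.69-fold in Matrigel), the receptor kinase gene Erbb3 (16.5- and 8.56-fold), Cd302 (10.8- and 6.74-fold) and the interleukin receptor gene Il13ra1 (7.19- and 5.40-fold). Their basal levels, 6.28 (Cd302) to 7.67 (Epcam), may be background, so these folds can be too small and the genes are not ranked. Enpep, also among the 15 on average, rose mainly in 9A1. It rose there by 6.505 in aggregates and 3.05 in Matrigel, against 0.43 and 0.31 in 14B3. The surface list as a whole passed for Matrigel against basal, with 46 genes higher and 25 lower, 51 and 28 adjusted over the list alone (adjusted p = 0.0334; adjusted p = 0.373 with an estimated correlation), but not without basal_9A1 replicate 1 (0.0532), basal_14B3 replicate 1 (0.0575), Matrigel_9A1 replicate 1 (0.0591) or Matrigel_14B3 replicate 1 (0.0545). It did not pass for aggregates against basal (51 higher and 53 lower, adjusted p = 0.927) or for Matrigel against aggregates (41 higher and 28 lower, adjusted p = 0.112, median -0.02 and mean 0.10).

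Known progenitor markers split. Cd24a fell by 2.46 in aggregates and was at -0.30 in Matrigel (adjusted p = 0.63). Dlk1 was at 0.11 in aggregates (adjusted p = 0.693) and rose by 1.34 in Matrigel, and Prom1 rose by 0.48 and 0.72. Igdcc4 was at 0.03 (adjusted p = 0.954, but -0.9953 with adjusted p = 0.0041 in replicate 2 arrays only) and 0.59 (adjusted p = 0.217). Sox9, a bile duct and progenitor transcription factor, fell by 0.47 in aggregates. Of the 21 progenitor surface genes 3 rose and 10 fell in aggregates (adjusted p = 0.0854, but 0.0203 without aggregate_9A1 replicate 1 and 0.0456 without aggregate_14B3 replicate 1), and 5 rose and 4 fell in Matrigel (adjusted p = 0.625).

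Over all genes 1662 were higher in basal culture than in both others and 1532 were lower, where 415 and 400 would be expected if the calls were independent, and 24 moved in opposite directions. Both comparisons share the basal arrays, so all 12 arrays were also simulated with no gene changed. The 2 simulated comparisons correlated at 0.50 across genes, which are not independent replicates, against 0.88 observed. They shared 0.02 calls per draw, which follows from the lack of any change. The simulation therefore cannot say how many of the observed shared calls come from sharing the basal arrays. With aggregates and Matrigel each set against different basal arrays, 1695 to 2258 genes were called in both with the same sign. Surface genes made up no larger part of the genes higher in basal culture than others did (13.1% of the list against 13.4% of all genes; Fisher's exact test, two-sided, exact p = 1, odds ratio 0.97, 95% confidence interval 0.60 to 1.51). They were more frequent by the same test among genes lower in basal culture (19.7% against 12.4%, exact p = 0.00438, odds ratio 1.75, 1.18 to 2.55). In all 2 such tests were made. Fisher's test takes the genes as independent, which they are not, so its p-values can be too small and its intervals too narrow.

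**Figure D3:**
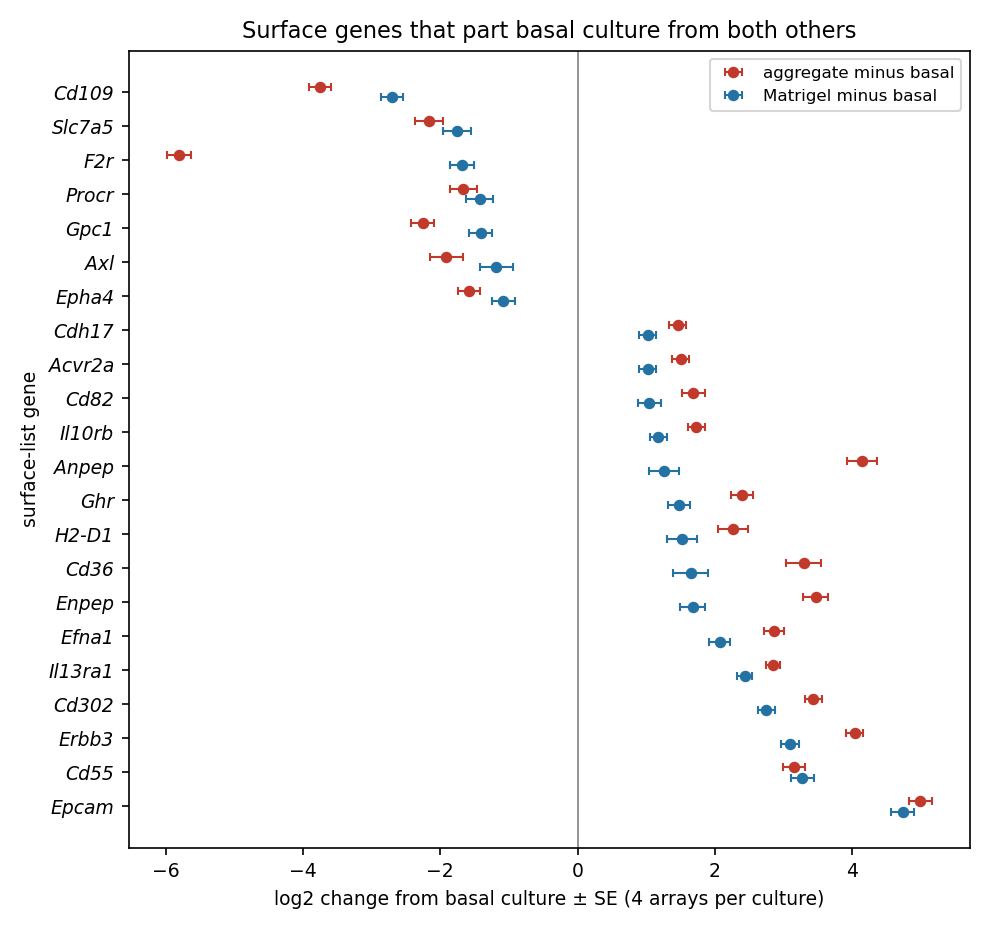
Log2 change from basal culture, with its SE, in aggregates (red) and Matrigel (blue) for the surface-list genes past adjusted p 0.05 and at least 1 log2 unit in both comparisons. Of these genes 7 lie below 0 in both cultures, from Cd109 to Epha4, and 15 lie above 0 in both, among them Epcam (31.9- and 26.6-fold).

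The cell lines were compared to ask how far these independent isolates differ. Ifi202b, an interferon-inducible gene (Entrez Gene 26388), had a mean linear intensity of 1548 in 9A1 and 56.2 in 14B3, a log2 difference (14B3 minus 9A1) of -4.78 ± 0.10 (SE, 6 against 6 arrays, adjusted p = 2.2e-10); its level in 14B3 may be background. The sex-linked genes differed: Xist, of the inactive X chromosome, was higher in 14B3 (11.85 against 8.76 log2 intensity), and the Y-linked genes Eif2s3y (4.22 against 8.46) and Uty (5.77 against 6.90) were lower. Of the 4 measured sex-linked genes, too few for a list test, Kdm5d was at 0.15 (adjusted p = 0.608). The line 14B3 was also higher in the peroxisomal thiolase gene Acaa1b (3.99), Cbr3 (3.07), the endoderm and endothelial transcription factor gene Sox17 (2.95), Pla2g4a (2.63) and Aspa (2.41). It was lower in Scara3 (-3.19), Tmem267 (-3.15), Fstl1 (-3.04) and the basement membrane gene Nid1 (-3.01).

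Averaged over cultures, matrix, pathway target and surface genes were lower as groups in 14B3 than in 9A1 by the list test. In basal, aggregate and Matrigel culture the matrix medians were -0.06, -0.02 and -0.47, so largest in Matrigel. In the same order the medians were -0.19, -0.03 and -0.24 for pathway targets. For surface genes they were 0.03, -0.05 and -0.07, so near 0 and not of 1 sign. Of 53 matrix genes 12 were lower and 0 higher, 22 and 1 adjusted over the list alone (adjusted p = 1.65e-12; adjusted p = 0.183 with an estimated correlation). Igfbp7 was at -2.18. Of 23 TGF-beta, Wnt and Hippo targets 7 were lower and 0 higher, 10 adjusted over the list alone (adjusted p = 9.39e-07; adjusted p = 0.189 with an estimated correlation). Ankrd1 was at -1.70, Ccn2 at -1.45 and Ccnd1 at -0.95. Of the 183 surface genes 24 were lower and 6 higher, 37 and 8 adjusted over the list alone (adjusted p = 4.13e-05; adjusted p = 0.183 with an estimated correlation). Enpep was at -3.00, Emp3 at -1.67 and the cadherin gene Cdh2 at -1.43. Of 21 progenitor surface genes 4 were lower and 2 higher, 6 and 2 adjusted over the list alone (adjusted p = 0.00155; adjusted p = 0.442 with an estimated correlation). Cd81 was at -0.49 and Prom1 at 0.47. The list median was -0.01 in basal culture, -0.18 in aggregates and -0.37 in Matrigel. Dlk1 was at -0.58 (adjusted p = 0.0892, but 0.0317 with the replicate block and 0.0157 without Matrigel_9A1 replicate 2).

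Cholesterol synthesis genes were higher as a group in 14B3: 7 of 19 were higher and 0 lower, 13 adjusted over the list alone (median 0.35, adjusted p = 7.48e-08; adjusted p = 0.384 with an estimated correlation). Stard4 was at 0.49. The list median was 0.66 in basal culture, 0.26 in aggregates and 0.08 in Matrigel. A further 5 lists passed by a margin that single arrays removed. Endothelial genes (3 of 23 higher, 0 lower, Sox17 the strongest, adjusted p = 0.0414) did not pass without basal_9A1 replicate 1 (0.0811), basal_14B3 replicate 2 (0.106), aggregate_9A1 replicate 1 (0.113), aggregate_14B3 replicate 2 (0.156), Matrigel_9A1 replicate 1 (0.348) or Matrigel_14B3 replicate 2 (0.341). The list had an adjusted p = 0.808 with an estimated correlation. Hypoxia genes (3 of 29 higher, 0 lower, Aldoc at 1.80, adjusted p = 0.0319) did not pass without aggregate_9A1 replicate 1 (0.273), aggregate_14B3 replicate 1 (0.24), Matrigel_9A1 replicate 1 (0.266) or Matrigel_14B3 replicate 2 (0.23), and the test turned in replicate 2 arrays only (0.979). The list had an adjusted p = 0.801 with an estimated correlation. Genes of unfolded protein and amino acid stress (5 of 28 higher, 0 lower, Chac1 at 0.82, adjusted p = 0.0214) did not pass without aggregate_9A1 replicate 2 (0.0556), aggregate_14B3 replicate 1 (0.0707), Matrigel_9A1 replicate 2 (0.0811) or Matrigel_14B3 replicate 1 (0.0776). The list had an adjusted p = 0.423 with an estimated correlation. Acute phase and complement genes (4 of 29 lower, 1 higher, Crp at -1.19 and C9 at 1.53, adjusted p = 0.0148) did not pass without basal_9A1 replicate 2 (0.052), basal_14B3 replicate 1 (0.0519), Matrigel_9A1 replicate 2 (0.14) or Matrigel_14B3 replicate 1 (0.062). The list had an adjusted p = 0.684 with an estimated correlation. Secreted hepatocyte proteins (4 of 39 lower, 1 higher, Serpina1b at -1.77, adjusted p = 0.0437) did not pass with the replicate block (0.0538) or without basal_9A1 replicate 2 (0.144), basal_14B3 replicate 1 (0.129), aggregate_9A1 replicate 1 (0.678), aggregate_14B3 replicate 2 (0.136), Matrigel_9A1 replicate 2 (0.222) or Matrigel_14B3 replicate 1 (0.105). The list had an adjusted p = 0.808 with an estimated correlation.

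In all, 318 genes were higher and 427 lower in 14B3 than in 9A1 (6.01% of the genes), 49 and 88 of them by at least 1 log2 unit; 1119 differed with the replicate block and 494 without basal_14B3 replicate 2. Within basal, aggregate and Matrigel culture alone 236 (358 with the replicate block), 189 and 467 genes differed. Albumin (-0.20, adjusted p = 0.871), Afp (0.21, adjusted p = 0.76) and Epcam (-0.08, adjusted p = 0.854) did not pass. The Afp value averages cultures in which the lines differed. Its response in 14B3 minus that in 9A1 was -3.29 in aggregates and -3.52 in Matrigel. It does not show like Afp levels within each culture.

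Few genes passed a test of the difference in response to culture between the 2 lines. All 58 genes that passed in aggregates and 84 of the 85 in Matrigel differed by at least 1 log2 unit. Smaller differences thus went almost wholly uncalled, and the low counts do not show that the lines responded alike. In aggregates the peptidase gene Enpep rose by 6.51 on the log2 scale in 9A1 and by 0.43 in 14B3, a difference of -6.07. The iron oxidase gene Heph (4.10 and 0.41 in 9A1 and 14B3, difference -3.68) and the lipase gene Pnliprp2 (3.96 and 0.48, difference -3.48) also rose less in 14B3. The claudin gene Cldn6 was at 0.22 in 9A1 and -3.34 in 14B3 (difference -3.55). The chemokine genes Cxcl1 (-2.98 and 0.06, difference 3.04) and Cxcl5 (-3.62 and -0.77, difference 2.84) were lowered in 9A1. In Matrigel the proteoglycan genes Srgn (-0.03 and 4.44, difference 4.47) and Nepn (0.04 and 3.52, difference 3.49) were raised in 14B3, and Ms4a6b in 9A1 (3.39 and 0.33, difference -3.06). In aggregates 58 genes passed, 118 with the replicate block, and 23 without basal_9A1 replicate 1, 36 without basal_9A1 replicate 2, 32 without basal_14B3 replicate 2, 98 without aggregate_9A1 replicate 1, 36 without aggregate_14B3 replicate 1 and 25 without aggregate_14B3 replicate 2. In Matrigel 85 genes passed, 165 with the replicate block, and 30 without basal_9A1 replicate 1, 47 without basal_9A1 replicate 2, 50 without basal_14B3 replicate 1 and 44 without basal_14B3 replicate 2.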

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

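The tests on the hybridisation controls and on RNA degradation were chosen only after the result was seen.

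Responses to culture that differed between the lines by the test of the difference were listed for the named genes, as the log2 response of 14B3 minus that of 9A1. In aggregates against basal culture the difference was positive for Cxcl1 (3.04), Cxcl5 (2.84), Fstl1 (2.84), Pigr (2.56), Thbd (2.51), Nepn (2.44), Acaa1b (2.42), 2010204K13Rik (2.20) and Irgm1 (1.39). It was negative for Enpep (-6.07), Heph (-3.68), Cldn6 (-3.55), Pnliprp2 (-3.48), Afp (-3.29), Fabp1 (-3.14), Ms4a6b (-2.34), Pla2g4a (-2.06), Chac1 (-1.65) and Csf1r (-1.46). In Matrigel against basal culture it was positive for Srgn (4.47), 2010204K13Rik (3.90), Nepn (3.49), Adh1 (3.06), Cxcl5 (2.55), C9 (2.51), Cxcl1 (2.18), Sox17 (2.17), Aspa (1.99), Acaa1b (1.59) and Cd34 (1.56). It was negative for Afp (-3.52), Fabp1 (-3.14), Ms4a6b (-3.06), Lamb3 (-2.82), Enpep (-2.74), Fbln2 (-2.61), Heph (-2.58), Cldn6 (-2.44), Tff3 (-2.31), Crp (-2.30), Tnnt2 (-1.90), Chac1 (-1.84), Ncam1 (-1.77), Nid1 (-1.71), Ifi202b (-1.70) and Lss (-1.23).

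Single arrays were left out for the 4 largest differences in each direction and culture, and the calls of 6 of these genes were then lost. Fstl1 in aggregates was lost without basal_9A1 replicate 1 (adjusted p = 0.181), basal_9A1 replicate 2 (0.0543), basal_14B3 replicate 2 (0.171), aggregate_14B3 replicate 1 (0.107), aggregate_14B3 replicate 2 (0.122) or either Matrigel_14B3 array (0.0528). Pigr was lost without each of those, with adjusted p = 0.126, 0.109, 0.182, 0.119, 0.0663 and 0.0528 in the same order, and without basal_14B3 replicate 1 (0.0789) or aggregate_9A1 replicate 1 (0.054). In Matrigel, Adh1 was lost without basal_9A1 replicate 1 (0.0672), basal_9A1 replicate 2 (0.053), basal_14B3 replicate 2 (0.0636) or Matrigel_14B3 replicate 2 (0.0541). Afp was lost without any 1 basal array (0.0568, 0.053, 0.0602 and 0.0529 for replicate 1 and 2 of 9A1, then of 14B3), Matrigel_9A1 replicate 2 (0.0605) or Matrigel_14B3 replicate 1 (0.0538). Fabp1 was lost without basal_9A1 replicate 1 (0.0703), Matrigel_9A1 replicate 2 (0.058) or Matrigel_14B3 replicate 1 (0.0529). Lamb3 was lost without any 1 of the 8 basal and Matrigel arrays, with adjusted p from 0.0672 (without Matrigel_14B3 replicate 1) to 0.178 (without Matrigel_9A1 replicate 1).

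Control probe sets outside the main measurement differed between replicate numbers: the 18S ribosomal RNA control was higher in replicate 2 in 6 of 6 groups, by 1.34 on average (exact sign test, two-sided, exact p = 0.0313), and the 18 bacterial and phage hybridisation controls by 0.70 on average (6 of 6, exact p = 0.0313). Over genes, with the 6 groups in the model, replicate 2 arrays were higher in 1271 genes and lower in 929, 3 of them by at least 1 log2 unit, and the endothelial (median 0.24, adjusted p = 6.79e-05), haematopoietic (0.16, 0.00154), stellate cell (0.19, 0.0243), hypoxia (0.17, 0.0133) and interferon (0.11, 0.0337) lists were higher, none with an estimated correlation (adjusted p = 0.774 to 0.834). RNA degradation is argued against by the 3' minus 5' differences of the actin and GAPDH controls, which moved by 0.07 and -0.05 (mean 0.00782), so in opposite directions, and by at most 0.16 in any group (actin). A hybridisation or labelling batch may contribute, since the controls that carry no cell RNA were higher in replicate 2 in 6 of 6 groups, and a difference in proliferation stays open, with a median of -0.14 over the proliferation list (adjusted p = 0.00182; adjusted p = 0.834 with an estimated correlation). The labels give no further grouping of the arrays, no other biological explanation was tested, and each group holds 1 array of each number.

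Other splits of the same arrays were run for each comparison, for cultures with no other term and for line with culture as a term. Among the splits run, the real one gave the most genes in each comparison. It called 5785 in aggregates against basal (highest of the others 10), 2917 in Matrigel against basal (79) and 2341 in Matrigel against aggregates (66), each 1 of 35 splits. For line it called 478 (11), 1 of 100 drawn splits. The numbers pair the arrays, so the real split was also compared with those that part every pair of like number. For each comparison of cultures these are 8 with the real one, too few for a share under 0.05, with a highest other of 0. For line they are 32, of which only the real one gave as many (highest other 10). That is the smallest share 32 splits can give, and the pairing was itself found in these data. Chance is thus argued against for line but not excluded. The remaining splits put both arrays of some pair on 1 side. The split of all 12 arrays by replicate number, outside those drawn, called 1379 genes against 478 for line, which points to a structure of the samples by number; with the replicate block 1119 genes differed between the lines.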

How the results depend on the processing

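Chosen only after the data were seen were the block over both lines, the arrays of 1 replicate number only and leaving out both arrays in doubt (aggregate_14B3 replicate 2 and Matrigel_14B3 replicate 1). Of 300 named gene results, 271 kept direction and call on leaving out any 1 array, and of 84 list results 63 did. Over the other settings, 3854 of 4209 gene comparisons and 1218 of 1386 list comparisons kept both; 337 and 139 lost the call, 15 and 27 gained it. The replicate block within each line changed no call of a named gene or list beyond those given in the report. Scaling the arrays otherwise left each count within 1.5 times. Reversed were the secreted protein list, Matrigel minus aggregate (-0.01943), and the hypoxia list by line (0.007443), where the test turned but the median did not, and Igdcc4 in aggregates (-0.9953, adjusted p = 0.0041), all with replicate 2 arrays only; Alb, Matrigel minus aggregate (-0.9795, adjusted p = 0.0141, replicate 1 arrays only); and H2-D1 by line (-0.08042, mean of its probe sets). The cause was not tested.

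Counts moved by over 1.5 times as follows. With every probe set tested, aggregate minus basal gave 9930, Matrigel minus basal 5798, Matrigel minus aggregate 5638 and line 1132; within lines 7837 and 6927 (aggregate, 9A1 and 14B3) and 3385 and 3136 (Matrigel); higher in basal 2902; more features were tested. With a change of at least 1 log2 unit they were 1935, 747, 572 and 137, within lines 2142, 1825, 846 and 738, and 248 higher in basal, by construction fewer. With replicate 2 arrays only, Matrigel minus basal gave 1220, Matrigel minus aggregate 936, line 5 and higher in basal 621; with replicate 1 arrays only, line gave 20 and higher in basal 1092; both use fewer samples. The replicate block within each line gave 1119 for line, 358 for line within basal culture, and 118 and 165 for the differences in response (aggregate, Matrigel), and the block over both lines 5146 for Matrigel minus aggregate, 1245 for line, 118 and 186. Genes above the median level gave 479 for line, 19 and 37, fewer genes being tested; an additive fit gave 478 for line; leaving out both arrays in doubt gave 479 for line and 30 for the response to aggregates. The cause was not tested for the block and the additive fit. Of 84 list tests 41 passed, and 0 with an estimated correlation, with or without the block.

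Leaving out 1 array at a time, with the lone array of that group assumed to vary like the others, the counts ranged from 4894 to 5787 (aggregate minus basal), 2608 to 3592 (Matrigel minus basal), 2399 to 3710 (Matrigel minus aggregate), 494 to 747 (line), 23 to 98 and 30 to 105 (responses), 3241 to 4635 and 2873 to 4148 (aggregate in 9A1 and 14B3), 981 to 2246 and 907 to 2097 (Matrigel in 9A1 and 14B3), 1144 to 1677 (higher in basal) and 35 to 42 (lists). The additive, culture-only and single-number fits have no term for a difference in response and give no value for it. Signal over background limits dim genes, such as most stromal and blood cell markers here.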

Other observations

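The added gene lists and the tests on them were chosen only after the genes with the largest changes had been seen.

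Genes of the intestinal enterocyte, the absorptive cell of the gut lining, rose as a group in both cultures. Of 47 measured members, 15 were seen before the list was written; 40 rose and 0 fell in aggregates (median log2 change 3.07) and 38 rose and 0 fell in Matrigel (median 1.56). Of the 32 others 25 rose in aggregates (adjusted p = 1.75e-13 over 20 tests; adjusted p = 0.172 with an estimated correlation) and 24 in Matrigel (adjusted p = 3.1e-18; adjusted p = 0.17 with an estimated correlation). The sterol transporter gene Abcg5 rose by 6.42 in aggregates and 5.08 in Matrigel, the calcium-binding gene S100g by 5.98 and 5.05, the retinol-binding gene Rbp2 by 5.25 and 4.41, the mucin gene Muc13 by 4.65 and 3.52, and the brush border genes Cdhr5 by 4.20 and 3.24 and Vil1 by 4.05 and 3.25. Members such as Slc5a1, Slc26a3 and Car4 were at 0.22, 0.06 and 0.10 in aggregates with no call. Of the 47 members, 2 are also in the fixed hepatocyte lists and 9 in any fixed list. In Matrigel against aggregates 17 of the 32 were lower and 1 higher (adjusted p = 4.27e-07, and 0.306 with an estimated correlation). In 14B3 against 9A1 4 of the 32 were lower and 1 higher without the list passing (adjusted p = 0.1). With the members seen beforehand, 10 of 47 were lower and 3 higher in 14B3, and the list passed (adjusted p = 0.000201 over 36 tests, and 0.695 with an estimated correlation).

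Intestinal transcription factors rose in 8 of 11 cases in aggregates (adjusted p = 0.00704 over 36 tests, as for lists with no member left out; adjusted p = 0.147 with an estimated correlation), with Hnf4g at 3.39 and Creb3l3 at 2.13, and in 5 of 11 in Matrigel (adjusted p = 0.00736; adjusted p = 0.147 with an estimated correlation), with 1.71 and 1.58. Of the 18 visceral endoderm genes not seen beforehand, 10 rose and 2 fell in aggregates (adjusted p = 0.00927; adjusted p = 0.379 with an estimated correlation), with the transthyretin gene Ttr at 4.15, and 9 rose in Matrigel (adjusted p = 0.00168; adjusted p = 0.306 with an estimated correlation). Of all 23 members, 8 are in fixed lists. Stomach genes rose in 5 of 15 cases in Matrigel, with Anxa10 at 4.47 and Ctse at 2.51 (median 0.04, adjusted p = 0.0169; adjusted p = 0.815 with an estimated correlation). Without Anxa10, seen beforehand, 4 of 14 rose and the list did not pass (adjusted p = 0.0592 over 20 tests). In aggregates 6 of 15 rose without the list passing (adjusted p = 0.123). Lists that passed in neither culture were intestinal secretory cells (adjusted p = 0.264 in aggregates and 0.714 in Matrigel), exocrine pancreas (0.0922 and 0.296), kidney tubule (0.108 and 0.631), lung epithelium (0.408 and 0.955) and stromal reference genes (0.691 and 0.46).

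A hypothesis is that these cells may switch on part of an intestinal absorptive program in aggregates and Matrigel. Hepatocyte and visceral endoderm lists rose in the same comparisons. Whether the enterocyte members are also active in those cell types was not tested, beyond counting members shared between lists. The 32 members not looked at beforehand had medians of 2.20 and 1.43, at percentile 100 of 10000 random lists as dim in basal culture (highest 0.32 and 0.27), so a rise of dim genes at large is argued against. Cross-hybridisation within gene families is argued against by the 33 members outside the families, of which a share of 0.879 rose. Of 22 of these not looked at beforehand 18 rose. Each group holds 1 array of each number, so a shift by number alone could not make the rise. Over all 47 members, with those seen beforehand, the median was at least 1.29 in each of 8 single-array comparisons within a number. The 47 members had medians in aggregates of 3.07, 3.06 and 3.01 as deposited, shifted to a common median and with cyclic loess. In Matrigel the medians were 1.56, 1.51 and 1.52 in the same order. A role of Cdx1 and Cdx2 stays open: the largest change, of Cdx2 in aggregates, was 0.7674, Cdx2 was at 0.07 in Matrigel, and arrays cannot tell whether all cells or a part of them changed.

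The differences between the lines were weighed against 3 explanations. Gain or loss of whole chromosomes is argued against: a share of 0 of the called genes lies on an autosome whose median line difference exceeds 0.1 in all 3 cultures; chromosome 7 had the only negative median (-0.0205), with 65 called genes lower and 14 higher in 14B3 (427 and 318 over all genes), which stays open. Parental haplotype blocks or local copy number may contribute, since 57 pairs of neighbouring called genes had the same sign, against a median of 23 and a maximum of 43 in 10000 shuffles. Leaving out pairs whose symbols start alike, as in gene families, 44 remained (median 21 and maximum 36 in 1000 shuffles). Stromal cells in the 9A1 arrays cannot be told apart from a difference between the lines. The 13 stromal reference genes were lower as a list (adjusted p = 0.049, and 0.683 with an estimated correlation, mean -0.19). Their median was 0.001346, and only Col5a1 (-0.57) and Col5a2 (-0.90) passed. Of the 13 genes 12 are also in fixed lists, so the list is no independent test. The isolates did differ in sex-linked genes, with Xist at 3.09, Eif2s3y at -4.24 and Uty at -1.14, though Kdm5d was at 0.15 without a call. Whether a difference between the isolates themselves accounts for the other called genes stays open and was not tested further.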
